A study of Saccharomyces cerevisiae with 30 samples.

How the data were processed

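The data are gene FPKM values (fragments per kilobase of gene per 1e6 mapped fragments) made by the authors, in a table for each set, used as deposited. The submitters' processing notes name cutadapt 1.16, HISAT2 2.1.0, StringTie 1.3.3b and build R64, without roles, filters, strand setting or annotation. Counts were not analysed here, so depth and counting noise could not be read. Per the labels, cultures of 5 mL at 28 °C and 300 rpm reached an OD600 of 0.7 before the change of medium, and libraries were made from 1 µg of total RNA.

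Each table held 6101 genes, of which 6093 matched the reference gene table. In the table of the bromodomain set, 2 gene names had been turned into dates by a spreadsheet and were restored to OCT1 and MAY24, the names in the table of the Ada3 set. All columns of both tables were used.

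Values were taken as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over a set were tested (5830 in the Ada3 set, 5841 in the bromodomain set). In each set limma 3.58.1 (R 4.3.3, and version 1.17.8 of the package data.table) was fitted with 1 mean per group, a trend of the variance with the mean, and a spread shared by all groups of the set. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 per comparison. An interaction is the difference between the sucrose effects of a mutant and of its WT.

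Gene lists (45, written before the data were examined) were tested with camera at a preset correlation between genes of 0.01 if at least 5 members were tested, adjusted over lists, and again with the correlation estimated. The samples, comparisons, alternatives and the rule for naming genes were also set before the data were examined. The rule named NGG1, GCN5 and SPT7; per comparison the 6 largest rises and 6 largest falls among called protein-coding genes with a mean of at least 5 FPKM and groups that did not overlap; up to 4 called members with the largest change of each called list or list with at least 3 called members; and SUC2, HXT7, ADH2, HXK1, GAL1, HSP12, PHO84, INO1, marker genes and genes of the other mating type. Genes with smaller changes and most called lists, chiefly ones lost with an estimated correlation, were left out.

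Near-identical copies were found with BLAST 2.17.0 as genome matches of at least 90% identity over at least 50% of a gene. Python 3.11.15 and matplotlib 3.10.9 drew the figure. In simulated data with the spread of the real libraries, limma recovered 78, 98, 100 and 100% of genes changed by log2 0.3, 0.6, 1 and 2 for WT of the Ada3 set, and 44, 86, 94 and 100% for the Gcn5m interaction, with 4 to 9 false calls among unchanged genes over 5 comparisons. The alternatives were a pseudocount of 0.1, no filter or a filter of 5 FPKM, quantile normalization, median rescaling, a replicate block, only the compared groups in the fit, at least 2-fold changes, an estimated list correlation, and leaving out each library.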

Results

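RNA was sequenced from 30 libraries of the budding yeast strain BY4741 and of mutants of SAGA, a transcriptional coactivator that acetylates histones. Cells grown in rich medium with glucose were moved for 30 min to medium with 2% glucose or 2% sucrose. The Ada3 set held 12 libraries of wild type (WT) and Ada3-3KR, an acetylation mutant of the SAGA subunit Ada3. The bromodomain set held 18 libraries of its own WT, of Gcn5m and of Spt7m, mutants of the bromodomains of the SAGA subunits Gcn5 and Spt7. Each of the 10 groups had 3 libraries. The labels do not say that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Values are FPKM, and depth is unknown. The FPKM of a library summed to between 1152780 and 1288949, and 22 to 33 genes were listed at 0. Libraries of 1 group correlated across genes at 0.994 to 0.997 in the Ada3 set and at 0.992 to 0.998 in the bromodomain set. A value in parentheses after a gene is its log2 change on the log2(FPKM + 1) scale ± SE, from 3 libraries against 3, past limma's test unless an adjusted p stands beside it. Between media, rose and fell mean higher and lower in sucrose than in glucose, both after 30 min. In the 12 comparisons between pairs of groups, the groups did not overlap for 38 to 78.7% of genes, where chance gives 10%. For 1 gene alone, an exact test of 3 against 3 cannot go below 0.1.

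The engineered loci lie in build R64 at NGG1 (YDR176W, chromosome IV, 814452 to 816560), which encodes Ada3, GCN5 (YGR252W, chromosome VII, 996869 to 998188) and SPT7 (YBR081C, chromosome II, 401253 to 405251), all protein-coding. The labels describe mutations of the proteins, so RNA levels do not check the genotypes. In the Ada3 set, NGG1 in replicates 1, 2 and 3 had FPKM of 17.3, 16.1, 15.2 in WT in glucose, 18.5, 17.3, 17.1 in WT in sucrose, 20.9, 22.1, 21.5 in Ada3-3KR in glucose and 23.4, 23.3, 24.9 in Ada3-3KR in sucrose. In the bromodomain set it had 17.4, 17.8, 19.4 in WT in glucose, 23.8, 22.4, 22.0 in WT in sucrose, 18.7, 17.96, 19.98 in Gcn5m in glucose, 20.9, 19.3, 22.3 in Gcn5m in sucrose, 17.7, 16.8, 17.4 in Spt7m in glucose and 18.2, 20.5, 17.9 in Spt7m in sucrose. GCN5 in the Ada3 set had FPKM of 29.6, 31.5, 28.3 in WT in glucose, 34.1, 31.0, 33.0 in WT in sucrose, 33.7, 35.7, 37.1 in Ada3-3KR in glucose and 36.6, 41.5, 38.9 in Ada3-3KR in sucrose. Its FPKM in the bromodomain set was 32.2, 26.4, 30.7 in WT in glucose, 33.5, 32.5, 35.2 in WT in sucrose, 17.1, 21.1, 21.5 in Gcn5m in glucose, 21.6, 21.4, 21.9 in Gcn5m in sucrose, 22.9, 21.7, 22.1 in Spt7m in glucose and 21.6, 25.0, 27.3 in Spt7m in sucrose. SPT7 in the Ada3 set had FPKM of 19.5, 21.9, 21.4 in WT in glucose, 19.9, 19.96, 18.8 in WT in sucrose, 21.1, 24.2, 24.2 in Ada3-3KR in glucose and 24.1, 22.9, 22.8 in Ada3-3KR in sucrose. In the bromodomain set SPT7 had 22.7, 21.9, 21.4 in WT in glucose, 28.3, 25.9, 27.5 in WT in sucrose, 18.7, 21.6, 23.9 in Gcn5m in glucose, 21.9, 25.4, 24.8 in Gcn5m in sucrose, 19.9, 19.9, 20.6 in Spt7m in glucose and 23.9, 25.6, 27.2 in Spt7m in sucrose. NGG1 was higher in Ada3-3KR than in WT in glucose (0.39 ± 0.06) and in sucrose (0.42 ± 0.06). GCN5 was lower in Gcn5m in glucose (-0.56 ± 0.09) and sucrose (-0.62 ± 0.09), and in Spt7m in glucose (-0.40 ± 0.09) and sucrose (-0.44 ± 0.09). Also higher in Ada3-3KR were GCN5 in glucose (0.25 ± 0.06) and sucrose (0.25 ± 0.06) and SPT7 in sucrose (0.24 ± 0.06). In sucrose, SPT7 was lower in Gcn5m (-0.17 ± 0.08) and NGG1 in Spt7m (-0.26 ± 0.07). NGG1 (Spt7m against WT in sucrose) lost its call with quantile normalization (-0.13, adjusted p = 0.0907). SPT7 (Gcn5m against WT in sucrose) lost its call with no filter, quantile normalization and median rescaling (-0.09 to -0.17, adjusted p = 0.0542 to 0.288) and without Gcn5m in sucrose replicate 1 or 3 or WT in sucrose replicate 1 or 3 (-0.11 to -0.20, adjusted p = 0.0530 to 0.233).

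The first comparison asked how WT of the Ada3 set differed between sucrose and glucose. SUC2 (YIL162W, chromosome IX, 37385 to 38983), which encodes invertase, went from 132 ± 7.50 to 1095 ± 36.6 FPKM (SD, n = 3). Large rises were in the respiratory growth gene RGI2 (3.13 ± 0.08), the propionate metabolism gene PDH1 (2.80 ± 0.08) and the mitochondrial citrate synthase gene CIT3 (1.55 ± 0.15). Large falls were in the low-affinity glucose transporter gene HXT3 (-2.05 ± 0.03) and in YER053C-A (-1.65 ± 0.09), CIP1 (-1.58 ± 0.06) and YOL014W (-1.53 ± 0.10). Of 22 gluconeogenesis and glyoxylate cycle genes, 22 rose and 0 fell (22 and 0 adjusted over the list alone), among them the acetate transporter gene ADY2 (3.33 ± 0.11), the lactate and pyruvate transporter gene JEN1 (2.96 ± 0.05), the phosphoenolpyruvate carboxykinase gene PCK1 (2.49 ± 0.09) and the malate synthase gene MLS1 (2.38 ± 0.08). Their median was 1.41, or 1.34 relative to all genes (camera, adjusted p = 7.02e-17, and adjusted p = 0.00842 with an estimated correlation).

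Heat shock chaperone genes had a median of -0.38, or -0.45 relative to all genes (camera, adjusted p = 8.01e-14, and adjusted p = 0.0263 with an estimated correlation). Of the 22 tested, 2 rose and 18 fell (3 and 18 adjusted over the list alone). Among 32 general stress genes, 2 rose and 25 fell (2 and 25 adjusted over the list alone), and the median was -0.36, or -0.43 relative to all genes (camera, adjusted p = 3.06e-17, and adjusted p = 0.00334 with an estimated correlation). They included the small heat shock protein gene HSP26 (-1.56 ± 0.04) and the cytosolic catalase gene CTT1 (-1.44 ± 0.04). Single genes that also rose were the sodium-coupled phosphate transporter gene PHO89 (2.1 ± 0.05), the proline permease gene PUT4 (1.68 ± 0.08), the invertase gene SUC2 (3.04 ± 0.05), the maltose activator gene MAL33 (1.5 ± 0.05), the maltase gene MAL12 (1.45 ± 0.07), the glycine decarboxylase gene GCV2 (1.58 ± 0.04), the glutamate dehydrogenase gene GDH2 (1.56 ± 0.05), the serine hydroxymethyltransferase gene SHM2 (1.54 ± 0.03), the folate dehydrogenase gene MTD1 (1.52 ± 0.03), the homocysteine methyltransferase gene MHT1 (1.48 ± 0.11), the glycine cleavage gene GCV1 (1.43 ± 0.04) and the acyl-CoA oxidase gene POX1 (1.5 ± 0.07). Of the genes followed in every comparison, the high-affinity hexose transporter gene HXT7 (1.13 ± 0.03), the alcohol dehydrogenase gene ADH2 (1.07 ± 0.08), the hexokinase gene HXK1 (1.38 ± 0.03), the galactokinase gene GAL1 (0.32 ± 0.09), the membrane stress protein gene HSP12 (-1.21 ± 0.04), the high-affinity phosphate transporter gene PHO84 (0.44 ± 0.04) and the inositol synthesis gene INO1 (0.70 ± 0.09) changed. GAL1 lost its call with quantile normalization (0.19, adjusted p = 0.0941) and without WT in glucose replicate 3 (0.26, adjusted p = 0.0528). With limma, 2715 of 5830 genes passed, 1906 higher and 809 lower, 111 of them by at least 2-fold. Rescaling moved this to 1100 higher and 1503 lower after quantile normalization and 1216 higher and 1480 lower after median rescaling, and the median of all genes moved by -0.11 with quantile normalization. Of 44 lists, 22 were called, and 3 held with an estimated correlation.

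In Ada3-3KR, the same media were compared. SUC2 stood at 531 ± 29.1 FPKM in glucose and 1043 ± 28.2 in sucrose (SD, n = 3). Large rises were in PCK1 (2.48 ± 0.09), PHO89 (2.24 ± 0.05) and YGR079W (2.14 ± 0.13), and large falls in HXT3 (-3.19 ± 0.03), YER053C-A (-2.63 ± 0.09), FMP45 (-2.20 ± 0.07) and RTC3 (-2.18 ± 0.03). The ribosome biogenesis list had 75 genes, of which 70 rose and 0 fell (71 and 0 adjusted over the list alone), including the nucleolin-like gene NSR1 (1.77 ± 0.07). Its median was 0.63 (camera, adjusted p = 1.57e-19, and adjusted p = 0.0817 with an estimated correlation). The ribosome biogenesis repressor gene TOD6 (1.82 ± 0.09) also rose. Of 32 general stress genes, 0 rose and 32 fell (0 and 32 adjusted over the list alone), among them CTT1 (-2.40 ± 0.04), HSP12 (-2.14 ± 0.04), the aldehyde dehydrogenase gene ALD3 (-2.07 ± 0.07) and the reticulon gene RTN2 (-1.90 ± 0.04). Their median was -0.90 (camera, adjusted p = 1.81e-32, and adjusted p = 3.04e-04 with an estimated correlation).

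Heat shock chaperone genes had a median of -0.48 (camera, adjusted p = 1.89e-13, and adjusted p = 0.0408 with an estimated correlation). Of the 22 tested, 0 rose and 17 fell (0 and 17 adjusted over the list alone). Other changes included MLS1 (1.98 ± 0.08), PDH1 (1.87 ± 0.08), ADY2 (1.78 ± 0.11), the acetyl-CoA synthetase gene ACS1 (1.45 ± 0.07), the S-adenosylmethionine synthetase gene SAM2 (1.57 ± 0.05), the S-methylmethionine permease gene MMP1 (1.47 ± 0.05), the S-adenosylmethionine synthetase gene SAM1 (1.46 ± 0.04), PHM7 (-2.0 ± 0.09) and the thiol peroxiredoxin gene AHP1 (-1.63 ± 0.04). The genes read in every comparison included SUC2 (0.97 ± 0.05), HXT7 (0.25 ± 0.03), ADH2 (1.25 ± 0.08), HXK1 (0.54 ± 0.03), PHO84 (1.28 ± 0.04) and INO1 (0.87 ± 0.09), while GAL1 (-0.05 ± 0.09, adjusted p = 0.704) did not pass the test. HXT7 moved with quantile normalization (0.38, adjusted p = 4.76e-06). GAL1 passed with quantile normalization (-0.24, adjusted p = 0.0368). The limma test passed 2954 of 5830 genes (1920 higher, 1034 lower), 123 of them by at least 2-fold. With scaling the numbers were 1451 higher and 1450 lower after quantile normalization and 1455 higher and 1513 lower after median rescaling. Of 44 lists, 23 were called, and 2 held with an estimated correlation.

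In glucose, Ada3-3KR was compared with WT. SUC2 was higher in the mutant, at 531 ± 29.1 FPKM against 132 ± 7.50 in WT (SD, n = 3), a log2 difference of 2.0 ± 0.05. Large differences were in the acetyltransferase gene HPA3 (2.19 ± 0.08) and the cell cycle repressor gene YOX1 (2.05 ± 0.07), which were higher, and in the polyamine exporter gene TPO2 (-2.05 ± 0.06), the peroxisomal citrate synthase gene CIT2 (-2.02 ± 0.04), the low-oxygen mannoprotein gene DAN1 (-2.02 ± 0.08), YBR056W-A (-1.90 ± 0.05) and BSC1 (-1.86 ± 0.14), which were lower. The serine synthesis gene SER3 (6.06 ± 2.50) had a large value, but read from 0.451 to 201 FPKM among the 3 WT libraries and overlaps another feature, so its change is uncertain. SER3 lost its call with a pseudocount of 0.1, no filter, quantile normalization and median rescaling (adjusted p = 0.0519 to 0.0637) and without Ada3-3KR in glucose replicate 1, 2 or 3 or WT in glucose replicate 2 or 3 (4.86 to 6.08, adjusted p = 0.0920 to 0.157). Among 75 ribosome biogenesis genes, 0 were higher and 71 lower (0 and 71 adjusted over the list alone), and the median was -0.72 (camera, adjusted p = 3.96e-29, and adjusted p = 0.0776 with an estimated correlation). They included NSR1 (-1.99 ± 0.07), the ribosome export gene RRP12 (-1.34 ± 0.09) and the small-subunit assembly gene UTP10 (-1.33 ± 0.05).

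The general stress list had 32 genes, of which 30 were higher and 1 lower (30 and 1 adjusted over the list alone). Its median was 0.49 (camera, adjusted p = 3.24e-09, and adjusted p = 0.0323 with an estimated correlation). Single genes that were higher included GCV2 (2.05 ± 0.04), GCV1 (1.90 ± 0.04), the purine synthesis gene ADE17 (1.66 ± 0.03), the urea amidolyase gene DUR1,2 (1.57 ± 0.06), SHM2 (1.54 ± 0.03), the replication licensing gene CDC6 (1.47 ± 0.14), the general amino acid permease gene GAP1 (1.45 ± 0.04), the cohesin gene MCD1 (1.44 ± 0.07), the hexose transporter gene HXT4 (1.42 ± 0.03), the S-phase cyclin gene CLB6 (1.38 ± 0.15) and the Pho85 cyclin gene PCL1 (1.33 ± 0.07), and the sterol uptake regulator gene SUT1 (-1.38 ± 0.06) was lower. Differences were also measured for HXT7 (0.25 ± 0.03), HXK1 (1.02 ± 0.03), GAL1 (0.33 ± 0.09), HSP12 (1.26 ± 0.04), PHO84 (-0.71 ± 0.04) and INO1 (-0.42 ± 0.09), while ADH2 (-0.15 ± 0.08, adjusted p = 0.145) did not pass the test. ADH2 passed with quantile normalization (-0.23, adjusted p = 0.0494) and with median rescaling (-0.23, adjusted p = 0.0423). Of 5830 genes tested with limma, 3629 passed, 2343 higher and 1286 lower, with 144 at 2-fold or more. The split was 1926 higher and 1515 lower after quantile normalization and 1806 higher and 1668 lower after median rescaling. Of 44 lists, 20 were called, and 1 held with an estimated correlation.

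In sucrose, the same strains were compared again. SUC2 had 1043 ± 28.2 FPKM in Ada3-3KR and 1095 ± 36.6 in WT (SD, n = 3). Large differences were in CIT2 (-4.03 ± 0.04), YKR075C (-3.62 ± 0.08), SPO24 (-3.01 ± 0.05), the protein kinase gene RCK1 (-2.87 ± 0.05), ECM13 (-2.84 ± 0.09) and ICY1 (-2.50 ± 0.08), lower in the mutant, and in YOX1 (2.66 ± 0.07), GAP1 (2.02 ± 0.04), HPA3 (1.96 ± 0.08) and HLR1 (1.67 ± 0.17), higher. Of 22 gluconeogenesis and glyoxylate cycle genes, 2 were higher and 19 lower (2 and 19 adjusted over the list alone), among them JEN1 (-1.77 ± 0.05). Their median was -0.57 (camera, adjusted p = 2.93e-08, and adjusted p = 0.0592 with an estimated correlation). Cell cycle regulator genes had a median of 0.79 (camera, adjusted p = 1.3e-08, and adjusted p = 0.0592 with an estimated correlation). Of the 22 tested, 21 were higher and 1 lower (21 and 1 adjusted over the list alone), with PCL1 (2.21 ± 0.07), MCD1 (1.65 ± 0.07) and CLB6 (1.62 ± 0.15).

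Also higher were DUR1,2 (2.18 ± 0.06) and GCV2 (1.74 ± 0.04), and the proline oxidase gene PUT1 (-1.96 ± 0.08) was lower. Lower too were the respiratory activator gene HAP4 (-1.61 ± 0.04), SUT1 (-1.97 ± 0.06), TPO2 (-1.86 ± 0.06), the pheromone-regulated gene PRM4 (-1.79 ± 0.08) and the glycogen phosphatase regulator gene GAC1 (-1.62 ± 0.04), and the small ribosomal RNA genes RDN5-1 (-2.65 ± 0.12) and RDN5-2 (-1.79 ± 0.09), near-identical copies whose values are uncertain. Among the genes read throughout were HXT7 (-0.62 ± 0.03), HXK1 (0.17 ± 0.03), HSP12 (0.33 ± 0.04), PHO84 (0.13 ± 0.04) and INO1 (-0.24 ± 0.09), while SUC2 (-0.07 ± 0.05, adjusted p = 0.224), ADH2 (0.03 ± 0.08, adjusted p = 0.770) and GAL1 (-0.04 ± 0.09, adjusted p = 0.709) did not pass the test. SUC2 passed with median rescaling (-0.12, adjusted p = 0.0325). HXK1 moved with quantile normalization (0.32, adjusted p = 1.85e-05). PHO84 lost its call with median rescaling (0.07, adjusted p = 0.0746) and without Ada3-3KR in sucrose replicate 2 (0.10, adjusted p = 0.0537). INO1 lost its call without Ada3-3KR in sucrose replicate 1 or 2 or WT in sucrose replicate 1 or 3 (-0.21 to -0.25, adjusted p = 0.0605 to 0.0969). With limma, 3261 of 5830 genes passed, 1968 higher and 1293 lower, 145 of them by at least 2-fold. Rescaling moved this to 1583 higher and 1627 lower after median rescaling. Of 44 lists, 18 were called, and 0 held with an estimated correlation.

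The interaction asked whether the sucrose effect differed between Ada3-3KR and WT. It is the log2 change of the mutant minus that of WT, so a positive value is a more positive change in the mutant. The rise of SUC2 was smaller in Ada3-3KR, and the change was also more negative than in WT for YKR075C (-2.61 ± 0.12), the mitochondrial pyruvate carrier gene MPC3 (-2.36 ± 0.12), ECM13 (-2.21 ± 0.13), CIT2 (-2.01 ± 0.06), JEN1 (-1.81 ± 0.07), PUT4 (-1.59 ± 0.11) and ADY2 (-1.55 ± 0.15). It was more positive for YGR079W (2.11 ± 0.18), NSR1 (1.92 ± 0.10) and TOD6 (1.64 ± 0.13). Among 75 ribosome biogenesis genes, 73 had a more positive and 0 a more negative log2 change than in WT (73 and 0 adjusted over the list alone), and the median was 0.62 (camera, adjusted p = 1.19e-29, and adjusted p = 0.0603 with an estimated correlation). The general stress list had 32 genes, of which 0 had a more positive and 30 a more negative log2 change than in WT (0 and 31 adjusted over the list alone). Its median was -0.59 (camera, adjusted p = 1.36e-17, and adjusted p = 0.00311 with an estimated correlation). Of 22 gluconeogenesis and glyoxylate cycle genes, 0 had a more positive and 18 a more negative log2 change than in WT (0 and 18 adjusted over the list alone). Their median was -0.82 (camera, adjusted p = 5.69e-10, and adjusted p = 0.0498 with an estimated correlation). Respiratory chain and ATP synthase genes had a median of -0.32 (camera, adjusted p = 2.65e-11, and adjusted p = 0.0603 with an estimated correlation). Of the 36 tested, 0 had a more positive and 32 a more negative log2 change than in WT (0 and 35 adjusted over the list alone). Of the genes followed in every comparison, SUC2 (-2.07 ± 0.07), HXT7 (-0.88 ± 0.05), HXK1 (-0.85 ± 0.04), GAL1 (-0.37 ± 0.13), HSP12 (-0.93 ± 0.06) and PHO84 (0.84 ± 0.05) differed, while ADH2 (0.18 ± 0.12, adjusted p = 0.260) and INO1 (0.17 ± 0.12, adjusted p = 0.301) did not pass the test. GAL1 lost its call without Ada3-3KR in glucose replicate 2 or Ada3-3KR in sucrose replicate 3 or WT in glucose replicate 3 or WT in sucrose replicate 2 or 3 (-0.26 to -0.39, adjusted p = 0.0501 to 0.0937). The limma test passed 2264 of 5830 genes (1002 more positive, 1262 more negative), 102 of them by at least 2-fold. With scaling the numbers were 1231 more positive and 1091 more negative after quantile normalization. Of 44 lists, 25 were called, and 2 held with an estimated correlation.

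In the bromodomain set, WT was compared between the same media. SUC2 went from 64.8 ± 3.61 to 886 ± 20.4 FPKM (SD, n = 3). Large falls were in the plasma membrane heat shock gene HSP30 (-2.62 ± 0.05), YER053C-A (-2.60 ± 0.14), DAN1 (-2.58 ± 0.17) and CIP1 (-2.23 ± 0.08), and in the near-identical metallothionein copies CUP1-2 (-2.22 ± 0.06) and CUP1-1 (-2.17 ± 0.06), which are uncertain. RGI2 (4.51 ± 0.17) rose. Among 22 gluconeogenesis and glyoxylate cycle genes, 22 rose and 0 fell (22 and 0 adjusted over the list alone), and the median was 2.38, or 2.20 relative to all genes (camera, adjusted p = 3.15e-15, and adjusted p = 0.00193 with an estimated correlation). They included JEN1 (4.96 ± 0.06), ADY2 (4.89 ± 0.08), PCK1 (4.88 ± 0.10) and ACS1 (4.10 ± 0.06). The citric acid cycle list had 17 genes, of which 17 rose and 0 fell (17 and 0 adjusted over the list alone), including CIT3 (3.05 ± 0.14). Its median was 0.76, or 0.59 relative to all genes (camera, adjusted p = 7.75e-08, and adjusted p = 0.0465 with an estimated correlation). Of 19 beta-oxidation and peroxisome genes, 18 rose and 0 fell (18 and 0 adjusted over the list alone), among them POX1 (2.52 ± 0.08) and the peroxisomal reductase gene SPS19 (1.94 ± 0.08). Their median was 0.82, or 0.65 relative to all genes (camera, adjusted p = 2.93e-06, and adjusted p = 0.0181 with an estimated correlation). Iron regulon genes had a median of 0.70, or 0.53 relative to all genes (camera, adjusted p = 1.56e-08, and adjusted p = 0.0363 with an estimated correlation). Of the 23 tested, 23 rose and 0 fell (23 and 0 adjusted over the list alone), with the siderophore-retaining mannoprotein gene FIT2 (1.97 ± 0.08).

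Among 52 mitochondrial ribosome genes, 52 rose and 0 fell (52 and 0 adjusted over the list alone), and the median was 0.79, or 0.61 relative to all genes (camera, adjusted p = 2.96e-15, and adjusted p = 0.0181 with an estimated correlation). Further rises were in PUT4 (3.90 ± 0.07), GDH2 (2.0 ± 0.04), MHT1 (2.12 ± 0.10), MMP1 (2.1 ± 0.07) and PHO89 (2.17 ± 0.05). Falls included CTT1 (-2.07 ± 0.08) and HXT3 (-1.98 ± 0.05). The genes read in every comparison included SUC2 (3.75 ± 0.05), HXT7 (1.36 ± 0.05), ADH2 (2.30 ± 0.10), HXK1 (1.69 ± 0.04), GAL1 (0.31 ± 0.11), HSP12 (0.58 ± 0.04), PHO84 (0.37 ± 0.07) and INO1 (0.34 ± 0.10). GAL1 lost its call with quantile normalization (0.07, adjusted p = 0.624), with median rescaling (0.15, adjusted p = 0.280) and without WT in glucose replicate 3 or WT in sucrose replicate 1 (0.26 to 0.27, adjusted p = 0.0711 to 0.0758). PHO84 moved with median rescaling (0.20, adjusted p = 0.0157). INO1 lost its call with quantile normalization (0.14, adjusted p = 0.244) and with median rescaling (0.19, adjusted p = 0.102). Of 5841 genes tested with limma, 3894 passed, 2975 higher and 919 lower, with 258 at 2-fold or more. The split was 1517 higher and 1848 lower after quantile normalization and 1769 higher and 1686 lower after median rescaling, and the median of all genes moved by -0.20 with quantile normalization and -0.16 with median rescaling. Of 44 lists, 24 were called, and 7 held with an estimated correlation.

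Gcn5m was compared between the media as well. SUC2 went from 104 ± 3.01 to 689 ± 22.9 FPKM (SD, n = 3). Large falls were in YRO2 (-3.71 ± 0.08), HSP30 (-3.63 ± 0.05) and the cell wall gene PIR3 (-2.99 ± 0.05), and RGI2 (6.18 ± 0.17), CIT3 (5.41 ± 0.14), PUT4 (3.66 ± 0.07), the external NADH dehydrogenase gene NDE2 (2.96 ± 0.06) and the desiccation tolerance gene SIP18 (3.23 ± 0.15) rose. The gluconeogenesis and glyoxylate cycle list had 22 genes, of which 21 rose and 0 fell (21 and 0 adjusted over the list alone), including ADY2 (6.29 ± 0.08), JEN1 (5.63 ± 0.06), ACS1 (5.12 ± 0.06) and the carnitine acetyltransferase gene CAT2 (4.97 ± 0.07). Its median was 2.79, or 2.59 relative to all genes (camera, adjusted p = 2.48e-11, and adjusted p = 0.00552 with an estimated correlation). Of 19 beta-oxidation and peroxisome genes, 19 rose and 0 fell (19 and 0 adjusted over the list alone), among them POX1 (4.76 ± 0.08), the peroxisomal thiolase gene POT1 (3.74 ± 0.08), the enoyl-CoA isomerase gene ECI1 (3.59 ± 0.11) and the peroxisomal catalase gene CTA1 (3.54 ± 0.06). Their median was 1.90, or 1.71 relative to all genes (camera, adjusted p = 1.88e-08, and adjusted p = 0.00552 with an estimated correlation). Changes were also measured for SUC2 (2.71 ± 0.05), HXT7 (2.16 ± 0.05), ADH2 (3.59 ± 0.10), HXK1 (1.81 ± 0.04), GAL1 (0.94 ± 0.11), HSP12 (2.42 ± 0.04) and PHO84 (-1.65 ± 0.07), while INO1 (0.11 ± 0.10, adjusted p = 0.324) did not pass the test. With limma, 4323 of 5841 genes passed, 3048 higher and 1275 lower, 493 of them by at least 2-fold. Rescaling moved this to 1819 higher and 2199 lower after quantile normalization and 2056 higher and 2014 lower after median rescaling, and the median of all genes moved by -0.23 with quantile normalization and -0.19 with median rescaling. Of 44 lists, 24 were called, and 2 held with an estimated correlation.

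Spt7m was also compared between sucrose and glucose. Its SUC2 went from 83.1 ± 3.35 to 1028 ± 86.2 FPKM (SD, n = 3). Large rises were in RGI2 (6.75 ± 0.17), YGR067C (5.33 ± 0.07), CIT3 (5.24 ± 0.14), PUT4 (4.05 ± 0.07), the hexose transporter gene HXT5 (3.41 ± 0.08), NDE2 (3.35 ± 0.06) and SIP18 (5.03 ± 0.15), and the pyruvate decarboxylase gene PDC5 (-3.15 ± 0.10) fell. Gluconeogenesis and glyoxylate cycle genes had a median of 3.01, or 2.82 relative to all genes (camera, adjusted p = 7.54e-12, and adjusted p = 0.00585 with an estimated correlation). Of the 22 tested, 22 rose and 0 fell (22 and 0 adjusted over the list alone), with ADY2 (6.32 ± 0.08), JEN1 (5.95 ± 0.06), ACS1 (5.41 ± 0.06) and CAT2 (5.16 ± 0.07). Among 19 beta-oxidation and peroxisome genes, 19 rose and 0 fell (19 and 0 adjusted over the list alone), and the median was 1.89, or 1.70 relative to all genes (camera, adjusted p = 6.11e-08, and adjusted p = 0.00803 with an estimated correlation). They included POX1 (4.77 ± 0.08), POT1 (3.99 ± 0.08), ECI1 (3.51 ± 0.11) and CTA1 (3.29 ± 0.06). Among the genes read throughout were SUC2 (3.61 ± 0.05), HXT7 (2.14 ± 0.05), ADH2 (3.46 ± 0.10), HXK1 (2.04 ± 0.04), GAL1 (0.90 ± 0.11), HSP12 (2.64 ± 0.04), PHO84 (-0.36 ± 0.07) and INO1 (0.34 ± 0.10). PHO84 moved with quantile normalization (-0.62, adjusted p = 1.7e-07) and with median rescaling (-0.56, adjusted p = 4.01e-07). INO1 lost its call with quantile normalization (0.15, adjusted p = 0.164) and with median rescaling (0.16, adjusted p = 0.145). The limma test passed 4437 of 5841 genes (3013 higher, 1424 lower), 585 of them by at least 2-fold. With scaling the numbers were 1972 higher and 2286 lower after quantile normalization and 2140 higher and 2162 lower after median rescaling, and the median of all genes moved by -0.23 with quantile normalization and -0.19 with median rescaling. Of 44 lists, 24 were called, and 2 held with an estimated correlation.

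Gcn5m was compared with WT in glucose. URA3 (YEL021W, chromosome V, 116167 to 116970) had 0.493 ± 0.427 FPKM in WT and 428 ± 25.2 in Gcn5m (SD, n = 3), with a log2 difference of 8.21 ± 0.24. Lower were the dihydroorotate dehydrogenase gene URA1 (-3.29 ± 0.05) and the zinc homeostasis gene IZH4 (-3.71 ± 0.17) and the near-identical metallothionein copies CUP1-2 (-3.92 ± 0.06) and CUP1-1 (-3.78 ± 0.06), whose values are uncertain. The iron regulon list had 23 genes, of which 21 were higher and 1 lower (21 and 2 adjusted over the list alone), including FIT2 (3.52 ± 0.08), the siderophore-retaining mannoprotein gene FIT3 (2.96 ± 0.07), the siderophore transporter gene ARN2 (2.89 ± 0.05) and the iron-responsive mRNA-binding gene TIS11 (2.64 ± 0.06). Its median was 1.37, or 1.47 relative to all genes (camera, adjusted p = 9.87e-21, and adjusted p = 0.00289 with an estimated correlation). Of 52 mitochondrial ribosome genes, 52 were higher and 0 lower (52 and 0 adjusted over the list alone). Their median was 0.55, or 0.65 relative to all genes (camera, adjusted p = 2.87e-24, and adjusted p = 0.00289 with an estimated correlation). Phosphate use genes had a median of -1.15, or -1.05 relative to all genes (camera, adjusted p = 4.83e-09, and adjusted p = 0.0303 with an estimated correlation). Of the 21 tested, 0 were higher and 20 lower (0 and 20 adjusted over the list alone), with the secreted acid phosphatase gene PHO5 (-2.44 ± 0.07) and PHO11 (-1.99 ± 0.07).

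Outside these lists, the iron-limitation gene LSO1 (3.71 ± 0.29), AHP1 (2.26 ± 0.06) and the copper transporter gene CTR1 (2.13 ± 0.04) were higher, and the isopropylmalate isomerase gene LEU1 (-2.79 ± 0.08), the biotin synthase gene BIO2 (-2.52 ± 0.11), the dihydroxyacid dehydratase gene ILV3 (-2.43 ± 0.06), the ribonucleotide reductase gene RNR1 (-2.23 ± 0.08), CTT1 (-2.14 ± 0.08), DAN1 (-2.02 ± 0.17) and the fatty acid desaturase gene OLE1 (-1.94 ± 0.04) were lower. PHO11 has a near-identical copy and is uncertain. Of the genes followed in every comparison, SUC2 (0.68 ± 0.05), HXT7 (0.47 ± 0.05), ADH2 (0.25 ± 0.10), HXK1 (0.96 ± 0.04), GAL1 (-0.61 ± 0.11), HSP12 (0.36 ± 0.04) and PHO84 (-1.60 ± 0.07) differed, while INO1 (0.08 ± 0.10, adjusted p = 0.486) did not pass the test. ADH2 lost its call with no filter (0.25, adjusted p = 0.0572), with only the compared groups in the fit (0.25, adjusted p = 0.110) and without Gcn5m in glucose replicate 1 or 3 or WT in glucose replicate 1 or 3 (0.16 to 0.26, adjusted p = 0.0749 to 0.220), and it moved without WT in glucose replicate 2 (0.41, adjusted p = 3.07e-04). Of 5841 genes tested with limma, 3621 passed, 1216 higher and 2405 lower, with 190 at 2-fold or more. The split was 1710 higher and 1788 lower after quantile normalization and 1786 higher and 1718 lower after median rescaling, and the median of all genes moved by 0.11 with median rescaling. Of 44 lists, 22 were called, and 3 held with an estimated correlation.

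In sucrose, Gcn5m was compared with WT once more. URA3 stood at 1.38 ± 0.964 FPKM in WT and 242 ± 16.4 in Gcn5m (SD, n = 3), a log2 difference of 6.76 ± 0.24. Single genes with large differences were ECM13 (3.13 ± 0.06), RGI2 (2.90 ± 0.17), AHP1 (2.79 ± 0.06), YIG1 (2.78 ± 0.12) and CIT3 (2.82 ± 0.14), higher, and URA1 (-3.71 ± 0.05), LEU1 (-3.31 ± 0.08) and YRO2 (-3.19 ± 0.08), lower. The subtelomeric gene YIL177C (-7.23 ± 2.49) has near-identical copies, read from 0 to 398 FPKM among the WT libraries in glucose, and is uncertain. Among 21 phosphate use genes, 1 was higher and 19 lower (1 and 19 adjusted over the list alone), and the median was -1.35 (camera, adjusted p = 4.41e-09, and adjusted p = 0.0207 with an estimated correlation). They included PHO84 (-3.61 ± 0.07), PHO12 (-3.04 ± 0.06), PHO11 (-2.98 ± 0.07) and the phosphate regulator gene SPL2 (-2.64 ± 0.09). The beta-oxidation and peroxisome list had 19 genes, of which 18 were higher and 0 lower (18 and 0 adjusted over the list alone), including the peroxisomal beta-oxidation gene FOX2 (2.60 ± 0.04), CTA1 (2.56 ± 0.06), POT1 (2.53 ± 0.08) and POX1 (2.49 ± 0.08). Its median was 1.31 (camera, adjusted p = 1.21e-10, and adjusted p = 0.00383 with an estimated correlation). Of 21 purine synthesis genes, 1 was higher and 19 lower (1 and 19 adjusted over the list alone), among them MTD1 (-2.58 ± 0.05) and ADE17 (-2.41 ± 0.04). Their median was -0.96 (camera, adjusted p = 2.03e-08, and adjusted p = 0.0185 with an estimated correlation).

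Iron regulon genes had a median of 0.78 (camera, adjusted p = 7.1e-12, and adjusted p = 0.0185 with an estimated correlation). Of the 23 tested, 21 were higher and 1 lower (21 and 1 adjusted over the list alone). Also lower were RNR1 (-3.17 ± 0.08) and the cytochrome c gene CYC1 (-2.46 ± 0.13). The genes read in every comparison included SUC2 (-0.36 ± 0.05), HXT7 (1.27 ± 0.05), ADH2 (1.54 ± 0.10), HXK1 (1.08 ± 0.04) and HSP12 (2.20 ± 0.04), while GAL1 (0.03 ± 0.11, adjusted p = 0.824) and INO1 (-0.16 ± 0.10, adjusted p = 0.155) did not pass the test. With limma, 4125 of 5841 genes passed, 1638 higher and 2487 lower, 354 of them by at least 2-fold. Rescaling moved this to 2004 higher and 2103 lower after quantile normalization and 2032 higher and 2066 lower after median rescaling. Of 44 lists, 24 were called, and 6 held with an estimated correlation.

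Spt7m was compared with WT in glucose. URA3 had 10320 ± 1007 FPKM in Spt7m against 0.493 ± 0.427 in WT (SD, n = 3), a log2 difference of 12.80 ± 0.24. Single genes with large differences were LSO1 (3.31 ± 0.29), higher, and URA1 (-3.22 ± 0.05), IZH4 (-3.08 ± 0.17), CUP1-2 (-3.53 ± 0.06) and CUP1-1 (-3.41 ± 0.06), lower. YBR090C, which overlaps another gene and is uncertain, was higher (2.49 ± 0.91). Among 23 iron regulon genes, 21 were higher and 0 lower (21 and 0 adjusted over the list alone), and the median was 1.00, or 1.10 relative to all genes (camera, adjusted p = 1.91e-26, and adjusted p = 0.00107 with an estimated correlation). They included FIT2 (3.17 ± 0.08), FIT3 (2.59 ± 0.07), ARN2 (2.54 ± 0.05) and the siderophore transporter gene ARN1 (2.25 ± 0.06). The mitochondrial ribosome list had 52 genes, of which 49 were higher and 0 lower (49 and 0 adjusted over the list alone). Its median was 0.36, or 0.46 relative to all genes (camera, adjusted p = 1.17e-22, and adjusted p = 0.00414 with an estimated correlation). Of 21 phosphate use genes, 0 were higher and 19 lower (0 and 19 adjusted over the list alone), among them PHO5 (-2.61 ± 0.07), PHO11 (-2.21 ± 0.07) and PHO12 (-2.1 ± 0.06). Their median was -0.84, or -0.73 relative to all genes (camera, adjusted p = 4.21e-10, and adjusted p = 0.0191 with an estimated correlation). Further differences were in PDC5 (2.1 ± 0.10), BIO2 (-2.07 ± 0.11) and AHP1 (1.90 ± 0.06). Differences were also measured for SUC2 (0.36 ± 0.05), HXT7 (0.27 ± 0.05), HXK1 (0.46 ± 0.04), GAL1 (-0.44 ± 0.11) and PHO84 (-0.82 ± 0.07), while ADH2 (0.02 ± 0.10, adjusted p = 0.886), HSP12 (-0.06 ± 0.04, adjusted p = 0.278) and INO1 (0.14 ± 0.10, adjusted p = 0.237) did not pass the test. INO1 passed with quantile normalization (0.25, adjusted p = 0.0415), with median rescaling (0.25, adjusted p = 0.0409) and without WT in glucose replicate 3 (0.25, adjusted p = 0.0290). YBR090C lost its call without Spt7m in glucose replicate 1 or 3 or WT in glucose replicate 1, 2 or 3 (1.96 to 2.58, adjusted p = 0.0529 to 0.121). The limma test passed 3108 of 5841 genes (917 higher, 2191 lower), 97 of them by at least 2-fold. With scaling the numbers were 1338 higher and 1444 lower after quantile normalization and 1523 higher and 1192 lower after median rescaling, and the median of all genes moved by 0.11 with median rescaling. Of 44 lists, 17 were called, and 3 held with an estimated correlation.

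In sucrose, Spt7m was compared with its WT. URA3 had 8335 ± 1575 FPKM in Spt7m and 1.38 ± 0.964 in WT (SD, n = 3), a log2 difference of 11.84 ± 0.24. Single genes with large differences were SIP18 (2.95 ± 0.15), RGI2 (2.72 ± 0.17), ECM13 (2.64 ± 0.06), AHP1 (2.38 ± 0.06), CIT3 (2.32 ± 0.14), MSC1 (2.23 ± 0.08), HSP26 (2.19 ± 0.06) and CAT2 (2.08 ± 0.07), higher, and URA1 (-3.74 ± 0.05), lower. Ribosome biogenesis genes had a median of -0.66 (camera, adjusted p = 5.63e-17, and adjusted p = 0.0219 with an estimated correlation). Of the 75 tested, 0 were higher and 74 lower (0 and 74 adjusted over the list alone). Among 21 purine synthesis genes, 1 was higher and 20 lower (1 and 20 adjusted over the list alone), and the median was -1.08 (camera, adjusted p = 2.69e-09, and adjusted p = 0.0174 with an estimated correlation). They included MTD1 (-2.63 ± 0.05) and ADE17 (-2.60 ± 0.04). The beta-oxidation and peroxisome list had 19 genes, of which 18 were higher and 0 lower (18 and 0 adjusted over the list alone), including POT1 (2.61 ± 0.08), FOX2 (2.38 ± 0.04), POX1 (2.34 ± 0.08) and CTA1 (2.28 ± 0.06). Its median was 1.25 (camera, adjusted p = 7.33e-10, and adjusted p = 0.00548 with an estimated correlation).

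Of 22 gluconeogenesis and glyoxylate cycle genes, 16 were higher and 2 lower (16 and 2 adjusted over the list alone). Their median was 0.75 (camera, adjusted p = 1.35e-06, and adjusted p = 0.0219 with an estimated correlation). Phosphate use genes had a median of -1.04 (camera, adjusted p = 2.67e-08, and adjusted p = 0.0219 with an estimated correlation). Of the 21 tested, 1 was higher and 19 lower (1 and 20 adjusted over the list alone), with PHO12 (-2.96 ± 0.06), PHO11 (-2.74 ± 0.07) and PHM6 (-2.35 ± 0.16). Among the genes read throughout were SUC2 (0.21 ± 0.05), HXT7 (1.05 ± 0.05), ADH2 (1.18 ± 0.10), HXK1 (0.82 ± 0.04), HSP12 (2.0 ± 0.04) and PHO84 (-1.55 ± 0.07), while GAL1 (0.14 ± 0.11, adjusted p = 0.249) and INO1 (0.14 ± 0.10, adjusted p = 0.199) did not pass the test. GAL1 passed with quantile normalization (0.28, adjusted p = 0.0417). INO1 passed with quantile normalization (0.27, adjusted p = 0.0204) and with median rescaling (0.22, adjusted p = 0.0492). Of 5841 genes tested with limma, 4108 passed, 1683 higher and 2425 lower, with 283 at 2-fold or more. The split was 1976 higher and 2078 lower after quantile normalization and 2062 higher and 2005 lower after median rescaling. Of 44 lists, 27 were called, and 9 held with an estimated correlation.

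The interaction of Gcn5m asked whether its sucrose effect differed from that of WT. The change was more positive than in WT for EGO4 (3.15 ± 0.10), YIG1 (2.94 ± 0.17), the peroxisomal lipase gene LPX1 (2.43 ± 0.12) and CIT3 (2.37 ± 0.19), and more negative for PHO89 (-2.54 ± 0.07) and YJR120W (-2.43 ± 0.55). Among 19 beta-oxidation and peroxisome genes, 17 had a more positive and 0 a more negative log2 change than in WT (17 and 0 adjusted over the list alone), and the median was 1.01 (camera, adjusted p = 2.96e-13, and adjusted p = 0.00126 with an estimated correlation). They included FOX2 (2.80 ± 0.06), CTA1 (2.71 ± 0.09) and POX1 (2.25 ± 0.11). The histone list had 10 genes, of which 10 had a more positive and 0 a more negative log2 change than in WT (10 and 0 adjusted over the list alone), including the histone gene HTA2 (2.33 ± 0.07). Its median was 1.25 (camera, adjusted p = 5.28e-11, and adjusted p = 0.0255 with an estimated correlation). Of 21 purine synthesis genes, 0 had a more positive and 19 a more negative log2 change than in WT (0 and 19 adjusted over the list alone). Their median was -0.86 (camera, adjusted p = 3.1e-14, and adjusted p = 0.00206 with an estimated correlation). General stress genes had a median of 0.53 (camera, adjusted p = 7.16e-10, and adjusted p = 0.109 with an estimated correlation). Of the 32 tested, 23 had a more positive and 3 a more negative log2 change than in WT (24 and 3 adjusted over the list alone). Of the genes followed in every comparison, SUC2 (-1.04 ± 0.08), HXT7 (0.80 ± 0.06), ADH2 (1.29 ± 0.15), GAL1 (0.64 ± 0.16), HSP12 (1.84 ± 0.06) and PHO84 (-2.02 ± 0.09) differed, while HXK1 (0.12 ± 0.06, adjusted p = 0.113) and INO1 (-0.24 ± 0.14, adjusted p = 0.174) did not pass the test. HXK1 passed with quantile normalization (0.19, adjusted p = 0.0293) and without Gcn5m in glucose replicate 2 or Gcn5m in sucrose replicate 3 (0.15, adjusted p = 0.0430 to 0.0454). INO1 passed without WT in glucose replicate 3 (-0.35, adjusted p = 0.0303). With limma, 2431 of 5841 genes passed, 1220 more positive and 1211 more negative, 176 of them by at least 2-fold. Rescaling moved this to 1142 more positive and 1392 more negative after quantile normalization and 1145 more positive and 1353 more negative after median rescaling. Of 44 lists, 19 were called, and 3 held with an estimated correlation.

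For Spt7m the interaction was tested in the same way. The change was more positive than in WT for EGO4 (2.96 ± 0.10), YIG1 (2.87 ± 0.17) and DAN1 (2.60 ± 0.25), and more negative for PDC5 (-2.83 ± 0.15). Among 32 general stress genes, 30 had a more positive and 0 a more negative log2 change than in WT (31 and 0 adjusted over the list alone), and the median was 1.18 (camera, adjusted p = 1.75e-19, and adjusted p = 0.0204 with an estimated correlation). They included SIP18 (3.76 ± 0.21), HSP26 (2.92 ± 0.09) and RTN2 (2.89 ± 0.11). The beta-oxidation and peroxisome list had 19 genes, of which 15 had a more positive and 0 a more negative log2 change than in WT (17 and 0 adjusted over the list alone), including FOX2 (2.62 ± 0.06) and CTA1 (2.46 ± 0.09). Its median was 1.01 (camera, adjusted p = 5.56e-11, and adjusted p = 0.00245 with an estimated correlation). Of 21 purine synthesis genes, 1 had a more positive and 19 a more negative log2 change than in WT (1 and 19 adjusted over the list alone), among them ADE17 (-2.44 ± 0.06). Their median was -0.98 (camera, adjusted p = 2.67e-14, and adjusted p = 0.00245 with an estimated correlation). Ribosome biogenesis genes had a median of -0.40 (camera, adjusted p = 4.85e-17, and adjusted p = 0.0294 with an estimated correlation). Of the 75 tested, 0 had a more positive and 62 a more negative log2 change than in WT (0 and 68 adjusted over the list alone). Among 23 iron regulon genes, 3 had a more positive and 16 a more negative log2 change than in WT (3 and 16 adjusted over the list alone), and the median was -0.77 (camera, adjusted p = 6.69e-07, and adjusted p = 0.0437 with an estimated correlation). The genes read in every comparison included HXT7 (0.78 ± 0.06), ADH2 (1.162 ± 0.15), HXK1 (0.35 ± 0.06), GAL1 (0.59 ± 0.16), HSP12 (2.05 ± 0.06) and PHO84 (-0.73 ± 0.09), while SUC2 (-0.14 ± 0.08, adjusted p = 0.132) and INO1 (0.00 ± 0.14, adjusted p = 0.989) did not pass the test. SUC2 passed without Spt7m in sucrose replicate 3 (-0.21, adjusted p = 0.0151). The limma test passed 2773 of 5841 genes (1398 more positive, 1375 more negative), 197 of them by at least 2-fold. With scaling the numbers were 1303 more positive and 1544 more negative after quantile normalization and 1299 more positive and 1553 more negative after median rescaling. Of 44 lists, 23 were called, and 8 held with an estimated correlation.

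Gcn5m and Spt7m were compared directly in sucrose. URA3 was lower in Gcn5m, with a log2 difference of -5.09 ± 0.24, and so were LEU1 (-2.50 ± 0.08) and the cell wall mannoprotein gene TIR1 (-2.35 ± 0.10). The respiratory chain and ATP synthase list had 36 genes, of which 2 were higher and 32 lower (2 and 33 adjusted over the list alone), including CYC1 (-1.98 ± 0.13) and the internal NADH dehydrogenase gene NDI1 (-1.73 ± 0.08). Its median was -0.62 (camera, adjusted p = 1.45e-30, and adjusted p = 0.0207 with an estimated correlation). Of 32 general stress genes, 2 were higher and 23 lower (2 and 24 adjusted over the list alone), among them SIP18 (-2.09 ± 0.15). Their median was -0.37 (camera, adjusted p = 1.4e-16, and adjusted p = 0.0291 with an estimated correlation). Ergosterol synthesis genes had a median of -0.25 (camera, adjusted p = 1.25e-15, and adjusted p = 0.0207 with an estimated correlation). Of the 25 tested, 0 were higher and 18 lower (0 and 19 adjusted over the list alone), with the sterol desaturase gene ERG5 (-1.64 ± 0.08). Among 21 phosphate use genes, 0 were higher and 11 lower (0 and 13 adjusted over the list alone), and the median was -0.19 (camera, adjusted p = 1.64e-07, and adjusted p = 0.0380 with an estimated correlation). Also lower were the fructose bisphosphatase gene FBP1 (-1.91 ± 0.09) and PCK1 (-1.66 ± 0.10). Differences were also measured for SUC2 (-0.57 ± 0.05), HXT7 (0.22 ± 0.05), ADH2 (0.36 ± 0.10), HXK1 (0.26 ± 0.04), HSP12 (0.20 ± 0.04), PHO84 (-2.07 ± 0.07) and INO1 (-0.30 ± 0.10), while GAL1 (-0.12 ± 0.11, adjusted p = 0.518) did not pass the test. ADH2 lost its call without Gcn5m in sucrose replicate 1 or 2 or Spt7m in sucrose replicate 3 (0.30 to 0.34, adjusted p = 0.0670 to 0.109). INO1 lost its call with quantile normalization (-0.26, adjusted p = 0.0702) and without Gcn5m in sucrose replicate 1, 2 or 3 or Spt7m in sucrose replicate 1 or 3 (-0.23 to -0.32, adjusted p = 0.0570 to 0.173). Of 5841 genes tested with limma, 1151 passed, 483 higher and 668 lower, with 35 at 2-fold or more. The split was 642 higher and 595 lower after quantile normalization. Of 44 lists, 22 were called, and 8 held with an estimated correlation. Without Spt7m in sucrose replicate 3, 748 genes passed.

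**Figure D1:**
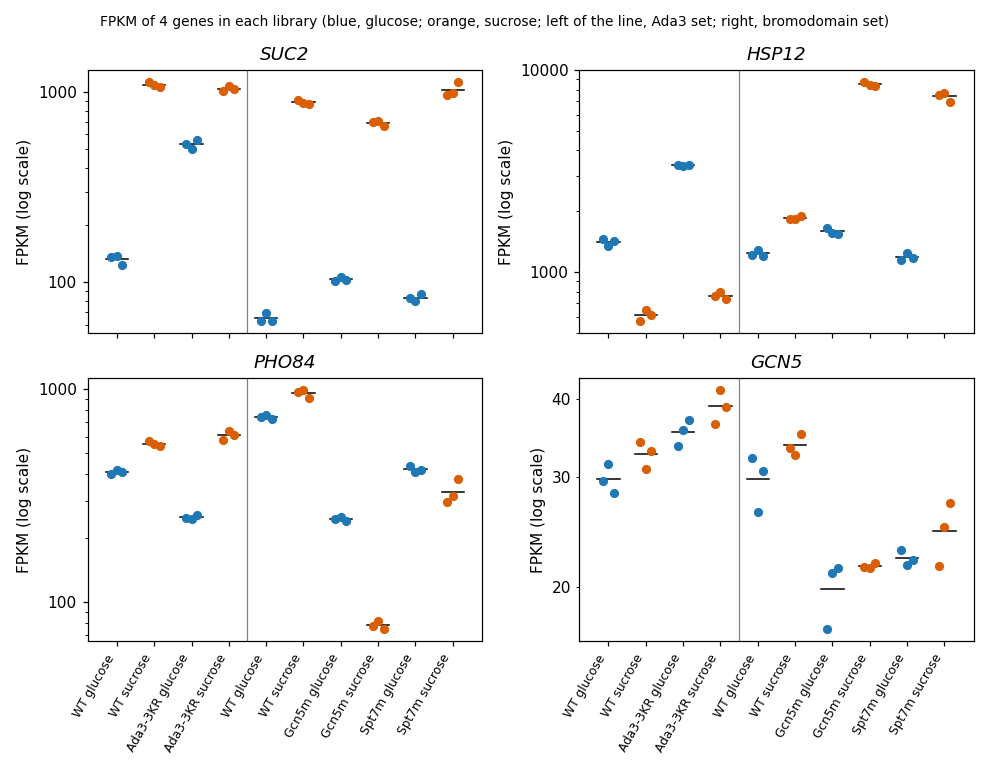
FPKM on a log axis of SUC2, HSP12, PHO84 and GCN5 in each library (points) of the 10 groups, with group means as lines. Mean SUC2 ran from 64.8 FPKM (WT in glucose, bromodomain set) to 1095 (WT in sucrose, Ada3 set), and Gcn5m in sucrose had the highest mean HSP12 (8504) and the lowest mean PHO84 (77.5).

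Common yeast marker genes, not only those of BY4741, were read in every comparison. LEU2 and MET17 were listed at 0 or near it, with a highest value of 0.136 FPKM for LEU2 and of 0 for MET17. In the Ada3 set, URA3 reached at most 0.398 FPKM in a library. Over the 15 comparisons the log2 change ranged for ADE2 from -1.75 to 1.15 (15 past the test), CAN1 from -0.81 to 0.85 (13 past the test) and HIS3 from -0.17 to 0.61 (9 past the test). It ranged for LYS2 from -0.45 to 0.99 (11 past the test) and TRP1 from -0.27 to 0.95 (9 past the test). BY4741 is of mating type a, yet SAG1 and HMLALPHA2, genes of the other mating type, had group means of up to 30.1 and 31.6 FPKM. For such genes, log2 changes ranged for STE3 from -1.23 to 0.36 (8 past the test), SAG1 from -0.49 to 0.75 (10 past the test) and MF(ALPHA)2 from -0.33 to 0.31 (2 past the test). Near-identical copies at the mating type loci are uncertain, with ranges for MATALPHA2 from -0.32 to 0.69 (5 past the test) and HMLALPHA2 from -0.38 to 0.73 (8 past the test). MF(ALPHA)1, MATALPHA1 and HMLALPHA1 were below the filter, at no more than 1.162, 0.539 and 0.678 FPKM. For Gcn5m between media, quantile normalization moved HIS3 to 0.34 (adjusted p = 0.00313), HMLALPHA2 to 0.47 (adjusted p = 5.94e-06) and MATALPHA2 to 0.46 (adjusted p = 2.57e-05). MF(ALPHA)2 (Gcn5m against WT in sucrose) lost its call with quantile normalization (-0.16, adjusted p = 0.276), with median rescaling (-0.24, adjusted p = 0.0797) and without Gcn5m in sucrose replicate 2 or WT in sucrose replicate 1, 2 or 3 (-0.29 to -0.33, adjusted p = 0.0520 to 0.0810). MF(ALPHA)2 (Spt7m between media) lost its call with quantile normalization (0.13, adjusted p = 0.347), with median rescaling (0.12, adjusted p = 0.370) and without Spt7m in glucose replicate 1 or 3 or Spt7m in sucrose replicate 3 (0.18 to 0.31, adjusted p = 0.0620 to 0.200). STE3 (WT between media in the bromodomain set) lost its call with quantile normalization (0.18, adjusted p = 0.193) and with median rescaling (0.23, adjusted p = 0.0866). TRP1 (Gcn5m against WT in glucose) moved with quantile normalization (-0.18, adjusted p = 0.00908) and with median rescaling (-0.16, adjusted p = 0.0120). Of the 139 genes named, 19 overlap another annotated feature or have a near-identical copy, so part of their value may come from elsewhere. Beyond those marked above, they are ALD3, GAL1, HPA3, HTA2, HXT7, MAL12, PHO12, PHO84 and TPO2.

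The WT sucrose responses of the sets, which share no library, correlated across 5817 genes at r = 0.807 (rho = 0.736). Of called genes, 1642 were higher in both (973 by chance for independent lists) and 529 lower in both (128). Genes called in both sets in opposite directions made up 1.81% of all genes (12.3%). By sign alone, called or not, 78.2% of genes went the same way. HSP12 went opposite ways (-1.21 in the Ada3 set, 0.58 in the other), and CTT1 fell in both. Genes are not independent replicates, so no p-value is given. In sucrose, the effect of Ada3-3KR correlated with that of Gcn5m at -0.279 and with that of Spt7m at -0.245. For Ada3-3KR and Gcn5m, 429 genes were higher in both (551 by chance for independent lists), 509 lower in both (552), and 27% of genes went opposite ways (20.7%). For Ada3-3KR and Spt7m these were 489 (566), 504 (539) and 26.3% (20.5%).

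The effects of Gcn5m and Spt7m in sucrose correlated at 0.897 over 5841 genes. Both used the same 3 WT libraries, and unchanged groups simulated against them gave a mean of 0.498 ± 0.131 (SD, 100 simulations). The covariance was 0.265, beside 0.00610 simulated. Of called genes, 1410 genes were higher in both (472 by chance for independent lists), 2146 lower in both (1033), and 1.18% of genes went opposite ways (23.9%). The 3 WT libraries were not split, as a part would hold only 1. Part of the excess may come from them or from the mutants' shared URA3 difference.

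Genes called in WT of either set were then read in the interactions of the other set, so that response genes came from other libraries. In Ada3-3KR, the 2970 genes that sucrose raised in WT of the bromodomain set had a median interaction of -0.08 (camera, adjusted p = 3.4e-04), and the 919 that it lowered had 0.07 (camera, adjusted p = 3.4e-04). In Gcn5m, the 1906 genes raised in WT of the Ada3 set had 0.04 (camera, adjusted p = 0.0318), and the 809 lowered had -0.12 (camera, adjusted p = 6.84e-04). In Spt7m the medians were 0.09 (camera, adjusted p = 5.4e-04) and -0.16 (camera, adjusted p = 3.4e-04). With an estimated correlation, the adjusted p of these 6 tests lay between 0.216 and 0.372. The preset correlation of 0.01 gave 334 list calls over the comparisons, and an estimated one gave 59.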

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

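The test of a mislabelled library, the test of the WT responses, the limit on what rescaling could do and the count of splits after removal of additive effects were chosen only after the result was seen. Differing sucrose effects of strains (interactions) drew attention, passing for 2264 genes in Ada3-3KR, 2431 in Gcn5m and 2773 in Spt7m.

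Log2 values in Ada3-3KR were YGR079W 2.11, NSR1 1.92, TOD6 1.64, PHO84 0.84, GAL1 -0.37, HXK1 -0.85, HXT7 -0.88, HSP12 -0.93, ADY2 -1.55, PUT4 -1.59, JEN1 -1.81, CIT2 -2.01, SUC2 -2.07, ECM13 -2.21, MPC3 -2.36 and YKR075C -2.61. In Gcn5m they were EGO4 3.15, YIG1 2.94, FOX2 2.80, CTA1 2.71, LPX1 2.43, CIT3 2.37, HTA2 2.33, POX1 2.25, HSP12 1.84, ADH2 1.29, HXT7 0.80, GAL1 0.64, SUC2 -1.04, PHO84 -2.02, YJR120W -2.43 and PHO89 -2.54. In Spt7m they were SIP18 3.76, EGO4 2.96, HSP26 2.92, RTN2 2.89, YIG1 2.87, FOX2 2.62, DAN1 2.60, CTA1 2.46, HSP12 2.05, ADH2 1.162, HXT7 0.78, GAL1 0.59, HXK1 0.35, PHO84 -0.73, ADE17 -2.44 and PDC5 -2.83. List medians were, in Ada3-3KR, general stress -0.59, gluconeogenesis and glyoxylate cycle -0.82, respiratory chain and ATP synthase -0.32 and ribosome biogenesis 0.62, in Gcn5m, beta-oxidation and peroxisome 1.01, general stress 0.53, histone 1.25 and purine synthesis -0.86, and in Spt7m, beta-oxidation and peroxisome 1.01, general stress 1.18, iron regulon -0.77, purine synthesis -0.98 and ribosome biogenesis -0.40. Genes that the other set's WT raised or lowered had medians of -0.0790 and 0.0732 in Ada3-3KR, 0.0421 and -0.119 in Gcn5m, and 0.0918 and -0.165 in Spt7m.

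Of 100 sample splits, 1, the real one, gave as many genes for the Ada3-3KR interaction (2264, highest other 1859), the fewest possible. For Gcn5m, 8 did (2431, highest other 4359), and for Spt7m 6 (2773, highest other 3149), so chance was not excluded. Chance between cultures stays open if replicates are technical. The 7 and 5 other splits that large mixed the strains unevenly between media, which turns a strain difference into an interaction. With additive strain and medium effects removed first, 1 of 100 splits, the real one, was as large for each of the 3 interactions (highest others 1, 699 and 995). The 12 comparisons of 3 libraries with 3 have 10 splits each, too few for a share under 0.05. The real split alone (1 of 10) gave the called number in each, from 1151 to 4437 genes, and the highest other split gave 0 or 1 gene.

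The first pattern was URA3 RNA in Gcn5m and Spt7m (428 and 10320 FPKM in glucose, a gap not explained) with low URA1. Against WT, URA1 differed by -3.29 and -3.71 in Gcn5m (glucose and sucrose) and -3.22 and -3.74 in Spt7m. The lowest URA3 value of the 12 mutant libraries (223 FPKM) was 96.8 times the highest of the 6 WT libraries (2.30). This argues against a single library swapped between WT and mutant. Swaps of whole groups or of media would not show in URA3, which defined the pattern. A restored URA3 marker in the mutant strains, which would relieve the induction of other pyrimidine genes, may explain it: URA4 (-1.44 and -1.66, -1.63 and -1.78) and URA10 were lower in 6 of 8 comparisons, exactly the number set in advance, but URA10 was higher in sucrose (0.33 in Gcn5m, 0.52 in Spt7m). Other pyrimidine genes, which that number left out, were lower in all 4 comparisons for URA2 (-0.85 to -1.29), URA6 (-0.22 to -0.50), URA7 (-0.45 to -1.04) and PPR1 (-0.31 to -0.40), while URA5 was lower in Gcn5m (-0.36 and -0.52) and higher in Spt7m (0.59 and 0.33). Effects of the marker and of the bromodomain mutations on other genes cannot be separated here, and no biological explanation was tested.

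The second pattern was an interaction of Ada3-3KR opposite to those of Gcn5m (r = -0.248) and Spt7m (r = -0.470). Median rescaling could not test scaling of the FPKM values, as it moves genes nearly alike and could have raised the Spt7m correlation to at most -0.452. Quantile normalization could have raised it to -0.181 at most, by a limit worked out from the observed values before and after it. That is past the bound set in advance against scaling, but short of the one set for scaling as the cause. The correlation stayed at -0.470 (jackknife SE 0.0616), below the bound against scaling. As the outcome for scaling could not occur, this leaves the cause undecided. A sucrose response reversed between the sets in every strain was argued against by the WT responses (r = 0.807). Scaling stays undecided for Spt7m and open for Gcn5m (-0.256 after quantile normalization, with no bound set). Also open are the opposite action of the mutations, the URA3 difference that Gcn5m and Spt7m share, and the growth state of the cultures, which were not tested.

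The third pattern was 6 genes, SER3, YBR090C, YCL020W, YIL177C, YRF1-3 and YRF1-6, that differed strongly among libraries of a group in 30 pairs of gene and group, by cutoffs not fixed in advance (highest at least 20 FPKM and over 10 times the lowest plus 0.5). Overlap with another annotated feature was 13-fold more frequent among them than among other genes (3 of 6 against 183 of 4753, Fisher's exact test, p = 0.00108), and near-identical copies 14.7-fold (4 of 6 against 216, Fisher's exact test, p = 6.2e-05). A narrower definition, run first (at least 100 and under 1 FPKM), gave 4 genes, with 5.30-fold (Fisher's exact test, p = 0.177) and 9.62-fold (Fisher's exact test, p = 0.00184), so the overlap result depended on the definition. Reads assigned among near-identical copies may explain the switching, overlap stays open, and no biological explanation was tested.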

How the results depend on the processing

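The count of genes without the switching genes was chosen after seeing the data. With a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization, median rescaling, only the compared groups in the fit, or without the switching genes where that was run, the 15 counts stayed within 1.5 times their values, and so did the numbers of passed tests of response genes and of list calls, while the 4 correlations moved by less than their jackknife standard errors, which for median rescaling says little, as it moves genes nearly alike.

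Requiring at least 2-fold leaves fewer genes by construction. In the Ada3 set, 111 and 123 were left for WT and Ada3-3KR between media. For Ada3-3KR against WT, 144 and 145 were left in glucose and sucrose, and 102 for its interaction. In the bromodomain set, 258, 493 and 585 were left for WT, Gcn5m and Spt7m between media. Against WT in glucose and sucrose, 190 and 354 were left for Gcn5m and 97 and 283 for Spt7m. Their interactions kept 176 and 197, and Gcn5m against Spt7m 35. With an estimated correlation, 0 of the 6 tests of response genes passed, against 6, and 59 list calls were made, against 334.

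When each library was left out in turn, counts in the Ada3 set ranged over 2305 to 2486 for WT and 2626 to 2781 for Ada3-3KR between media. For Ada3-3KR against WT they were 3346 to 3614 in glucose and 2932 to 3088 in sucrose, and 2024 to 2250 for its interaction. In the bromodomain set they were 3596 to 3719 for WT, 4138 to 4227 for Gcn5m and 4260 to 4295 for Spt7m between media. Against WT in glucose and sucrose, they were 3340 to 3481 and 3890 to 3944 for Gcn5m. For Spt7m they were 2724 to 2960 and 3889 to 3930. The interactions of Gcn5m and Spt7m gave 2196 to 2321 and 2595 to 2704, and Gcn5m against Spt7m gave 748 to 1022. Without Spt7m in sucrose replicate 3, Gcn5m against Spt7m fell to 748 genes from 1151, and the cause was not tested. The correlations ranged over 0.782 to 0.807 for the WT responses, -0.291 to -0.252 for Ada3-3KR with Gcn5m, -0.253 to -0.235 for Ada3-3KR with Spt7m and 0.874 to 0.911 for Gcn5m with Spt7m. Of the tests of response genes, 5 to 6 passed, and 330 to 339 list calls were made.

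The 414 gene values of the text were read under the alternatives 5704 times. Direction and side of the threshold held 5597 times, the call was lost 71 times and gained 15 times, and the sign changed 21 times, each time for a gene that had not passed the test, and the cause was not tested. ADH2 for Ada3-3KR against WT in sucrose was -0.00230 with quantile normalization and -0.0233 with median rescaling. HSP12 for Spt7m against WT in glucose was 0.0606 with median rescaling. INO1 was -0.0651 with quantile normalization and -0.0702 with median rescaling for Gcn5m between media, 0.0110 with quantile normalization for Gcn5m against WT in sucrose, and -0.00160 with a pseudocount of 0.1 and -0.0287 with median rescaling for the Spt7m interaction. Over libraries left out, ADH2 ranged over -0.0343 to 0.0948 for Ada3-3KR against WT in sucrose and -0.0638 to 0.181 for Spt7m against WT in glucose, GAL1 over -0.111 to 0.0593 for Ada3-3KR between media, -0.0711 to 0.00670 against WT in sucrose and -0.0115 to 0.0657 for Gcn5m against WT in sucrose, and INO1 over -0.113 to 0.0766 for the Spt7m interaction.

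With the replicate number as a block, the counts ranged from 1143 (Gcn5m against Spt7m) to 4442 (Spt7m between media) and stayed within 1.5 times their values. The numbers were not read as pairing the samples. Deviations of libraries with the same number correlated at -0.250 to 0.407 in the Ada3 set (mean 0.102, against -0.0514 for different numbers) and -0.428 to 0.336 in the bromodomain set (mean -0.0138, against 0.00710), so an effect of the number is not excluded in the Ada3 set. Each of these alternatives was set before the data were examined, except as said above, and was run. Depth is unknown, so what it limits could not be read.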

Other observations

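Proteasome genes, which encode the main protein-degrading machine, were higher in Ada3-3KR than in WT, with a median of 0.37 (camera, adjusted p = 3.68e-09, and adjusted p = 0.101 with an estimated correlation) in glucose and 0.33 (camera, adjusted p = 6.63e-10, and adjusted p = 0.110 with an estimated correlation) in sucrose. In Gcn5m they were also higher than in WT, with 0.32 (camera, adjusted p = 5.75e-13, and adjusted p = 0.0566 with an estimated correlation) in glucose and 0.32 (camera, adjusted p = 4.41e-09, and adjusted p = 0.0674 with an estimated correlation) in sucrose. Genes of vacuole, autophagy and proteolysis were higher than in WT with both strains in sucrose, with 0.43 (camera, adjusted p = 2.23e-06, and adjusted p = 0.0207 with an estimated correlation) in Gcn5m and 0.51 (camera, adjusted p = 3.03e-07, and adjusted p = 0.0206 with an estimated correlation) in Spt7m.

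In glucose, chosen after seeing the data, the effect of Ada3-3KR correlated with that of Gcn5m at 0.112 and with that of Spt7m at 0.0326.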
